A study of Mus musculus with 46 samples.

How the data were processed

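Libraries of 16 mice at postnatal day 23 were compared between p150-negative and p150-positive animals in liver, kidney and cerebellum, with genotype, tissue and animal taken from the labels. Per the labels, total RNA was extracted with TRIzol, treated with DNase and made into Nextera XT libraries. Per the submitters' processing notes, reads were handled with STAR 2.4.2a, HTSeq 0.4.1, Picard 1.134, SAMtools 1.2 and FastQC 0.11.3 on GRCm38 (mm10); the annotation release, the strand setting and the order of steps are not stated. The values deposited by the authors are raw counts of reads per gene, 1 column per library, and all 46 columns were matched to a sample with 0 left over. Every value is a whole number. Reads were not aligned again here, so neither RNA editing nor isoforms were analysed.

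The table held 53471 gene entries, of which 6 identifiers stood 2 times with identical counts and were used once, leaving 53465. Entries without a symbol numbered 3433 and held 0.267% of counts. Coordinates came from GENCODE M21, which holds 99.8% of the identifiers. Reads of near-identical genes (Mup, Ces3, Serpina1, Hba, Hbb, Oas1, Ifit3 and H2-Q families) may be shared or dropped by counting, so the values of single members of these families are uncertain. Library totals ran from 0.27 to 6.24 M counts (M, 1000000), with a median of 2.93 M. Per group they were 0.53 to 3.79 M in p150-negative and 1.68 to 4.3 M in p150-positive livers, 0.27 to 3.6 and 1.3 to 4.88 M in kidneys, and 0.94 to 5.47 and 2.32 to 6.24 M in cerebella. At 1 M counts, a gene at 10 CPM is read from about 10 counts. Counting intervals given in the text cover counting error alone, not the spread between animals.

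Genes were tested in each tissue with edgeR 4.0.16 (quasi-likelihood test, TMM normalization, filterByExpr by genotype with a minimum count of 10 and a minimum total of 15) in R 4.3.3. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in that tissue, and calls with an absolute log2 fold change of at least 1 were counted beside them. Log2 fold changes are p150-negative over p150-positive, with a standard error from the quasi-likelihood F statistic. CPM values are means and SD over animals, on library totals. The genotype effect was compared between tissues by the interaction of genotype and tissue in 1 fit per pair of tissues. The animal as a block was the alternative to that fit, because libraries of 1 animal in 2 tissues pair by its number. For the same animal, gene deviations from the group mean correlated from -0.014 to 0.25 between liver and kidney, from -0.006 to 0.254 between liver and cerebellum and from -0.186 to 0.214 between kidney and cerebellum. Overlap of calls was set beside the number for independent lists and tested with Fisher's exact test.

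Gene lists (48, with 945 members, 942 of them in the table) were fixed together with the tests, the alternatives and the rule for naming genes before the data were examined. Each was tested with limma 3.58.1 (camera with a preset correlation of 0.01, camera with an estimated correlation, and fry), adjusted over the lists of that tissue. Members are counted as called over all genes and as adjusted over the list alone. A library's score for a list is the mean log2 CPM (prior count 2) of its tested members. Scores were related within a genotype by Pearson's and Spearman's coefficients with exact permutation, and again without the 2 animals farthest from the median. Named genes are the 10 largest increases and 6 largest decreases per tissue with an adjusted p under 0.05, a mean log2 CPM of at least 1 and at least 75% of p150-negative animals on the called side of the p150-positive median. Sex-linked genes, predicted genes (Gm or Rik symbols) and antigen receptor segments were left out of that ranking. Also named are up to 4 members with the smallest adjusted p of each list discussed, 5 genes per direction of each interaction, and 21 genes named whatever they showed. Some genes that met these rules are not named in the text. In kidney and in the tissue-checked fits the same rule was applied to the tissue-checked values, after the data were seen; Havcr1, Lcn2 in kidney and Rbm3 in liver and cerebellum were also chosen after their values were seen.

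The tissue check summed the CPM of 4 identity genes per tissue in every library and failed a library under 10% of the median of its label. It was added as an alternative after the data were seen, and so were the leaving out of each library in turn (also from the tissue-checked kidney fit), of all libraries of animal 2 and of libraries under 1 M counts. The alternatives set in advance were size factors by RLE, DESeq2 1.42.0, limma's voom, no expression filter, a stricter filter, robust dispersion, the first part of the animal identifier as a block, log2 CPM of Xist as a covariate, and 1 fit of all tissues. The labels do not say what the identifier parts mark, and they do not give sex. By Xist against Y-linked genes the libraries of each of the 16 animals matched in sex, with Xist the higher in 5 of 8 p150-negative and 3 of 8 p150-positive animals. No 2 libraries of a group were alike beyond counting noise (smallest chi-square per gene 5.59).

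The code was tested on simulated data with the observed totals and spread. With all labelled libraries, 86.5% of 4-fold changes were recovered in liver, 36.4% in kidney and 85.0% in cerebellum, and with libraries that passed the tissue check 97.8%, 65.3% and 83.2%. Of 2-fold changes, 24.2%, 4.0% and 37.1% were recovered with all libraries. Between 2.2% and 5.1% of simulated calls were false. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.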

Results

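The series measured messenger RNA by sequencing in the liver, kidney and cerebellum of C57BL/6 mice at postnatal day 23. All animals carried the P195A change in Adar, the gene of ADAR1, an enzyme that edits adenosine to inosine in double-stranded RNA. P195A lies in the domain of ADAR1 that binds left-handed (Z-form) nucleic acids, and the interferon-inducible p150 isoform holds that domain. In 8 animals the other allele made no p150 (p150-negative), and in 8 it did (p150-positive). The comparison asks what gene expression follows from having the changed p150 alone, beside animals that also have an unchanged p150. The 46 libraries came from 16 animals: 8 p150-negative and 7 p150-positive livers, 7 and 8 kidneys, and 8 and 8 cerebella. Most animals gave all 3 tissues. Total counts, in units of 1000000 (M), ran from 0.53 to 4.3 M in liver, from 0.27 to 4.88 M in kidney and from 0.94 to 6.24 M in cerebellum. The median over all libraries was 2.93 M. The shallowest were the kidney library of animal 3 (0.27 M), the liver library of animal 16 (0.53 M) and the cerebellum library of animal 11 (0.94 M), all p150-negative.

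Genes that mark each tissue were checked first, because 5 libraries did not carry those of their label. In the other 41 libraries the summed level of the labelled tissue's identity genes (Alb, Apoa1, Serpina1c and Cps1 in liver; Umod, Slc34a1, Kap and Aqp2 in kidney; Pcp2, Gabra6, Cbln3 and Neurod1 in cerebellum) was at least 59.8% of the median of its label. In the 5 it was at most 0.827%. The library labelled liver of animal 2 held kidney genes at 8281 CPM (counts per 1000000), against at most 9.6 CPM in passing livers, and adrenal genes at 2602 CPM (at most 4.2), with Gpx3 as its most abundant gene. The library labelled kidney of animal 2 held stomach genes at 57880 CPM, led by Cym, the gene of the milk-clotting enzyme chymosin, at 18020 CPM, and Gkn1. The libraries labelled kidney of animal 11 and animal 12 held small intestine genes at 24846 and 15150 CPM, against at most 146 CPM in passing kidneys. That of animal 12 also held exocrine pancreas genes at 14355 CPM (at most 447). The library labelled cerebellum of animal 7 held Hox genes of the hindbrain and spinal cord at 116 CPM, against at most 9.8 CPM, with the myelin gene Mbp among its most abundant. Animals 2 and 11 are p150-negative, and animals 7 and 12 are p150-positive. Counts of called genes are therefore given over all labelled libraries, as planned, and again over the 41 libraries that passed this tissue check. Values of single genes in a tissue come from the tissue-checked fit unless stated otherwise, and that choice was made after the data were seen. Differences between tissues are given over all labelled libraries unless stated otherwise.

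**Figure D1:**
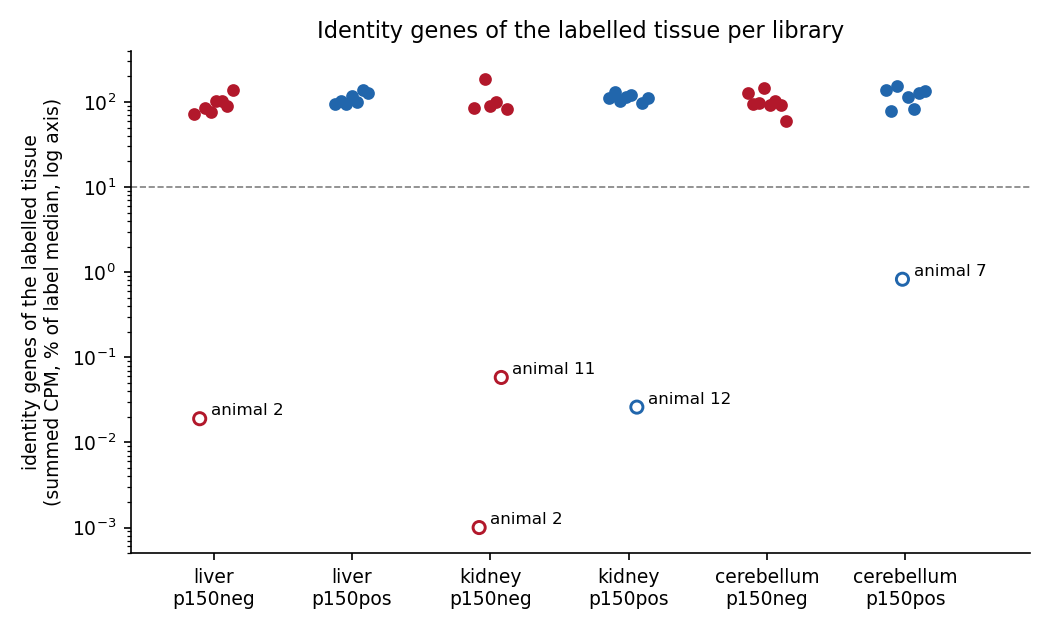
Summed CPM of the 4 identity genes of the labelled tissue in each library, as a percentage of the median of its label (log axis; the value of 0 of animal 2 is drawn at the bottom), by tissue and genotype. Filled points pass and open points fail the check, whose limit of 10% is the dashed line; the 41 passing libraries sit at 59.8% or more and the 5 failing ones at 0.827% or less.

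Adar itself (ENSMUSG00000027951, GRCm38 chromosome 3, 89715022 to 89753446, plus strand) was measured in every tissue and did not pass the test between genotypes in any. In passing livers it stood at 7.36 ± 4.48 CPM (SD, n = 7) in p150-negative and 11.8 ± 5.16 CPM (n = 7) in p150-positive animals. The values were 15.3 ± 9.52 (n = 5) and 19.7 ± 11.5 CPM (n = 7) in kidney, and 34.2 ± 22.2 (n = 8) and 23.9 ± 7.67 CPM (n = 7) in cerebellum. Over all labelled libraries the adjusted p was 0.364 in liver, 1.0 in kidney and 0.916 in cerebellum. Counts per gene sum over isoforms, so they are no direct check of the p150 genotype.

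In liver, p150-negative animals had more mRNA of interferon-stimulated, acute phase, neutrophil and macrophage genes and less of cholesterol synthesis, lipogenesis and growth hormone pathway genes than p150-positive animals. Lcn2, an iron-siderophore binding acute phase protein, stood at 3180 ± 1460 CPM (SD, n = 7) against 90.0 ± 85.9 CPM (n = 7), a log2 fold change of 5.17 ± 0.55 (SE; adjusted p = 3.26e-06). Asns, the asparagine synthetase gene that ATF4 activates, rose by 3.40 ± 0.34 (adjusted p = 1.86e-06). Msmo1, an enzyme of cholesterol synthesis, stood at 26.3 ± 19.0 CPM against 461 ± 161 CPM, a log2 fold change of -4.07 ± 0.36 (adjusted p = 4.83e-07). Each of these genes lay on the called side of the p150-positive median in 7 of 7 p150-negative livers. Over all labelled livers (8 against 7), 441 of 10041 tested genes were higher and 299 lower in p150-negative animals; 381 and 205 of them differed by a log2 fold change of at least 1. Without the library labelled liver of animal 2, which failed the tissue check, the counts were 683 higher and 469 lower of 9843, and these held 407 of the 441 and 293 of the 299.

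**Figure D2:**
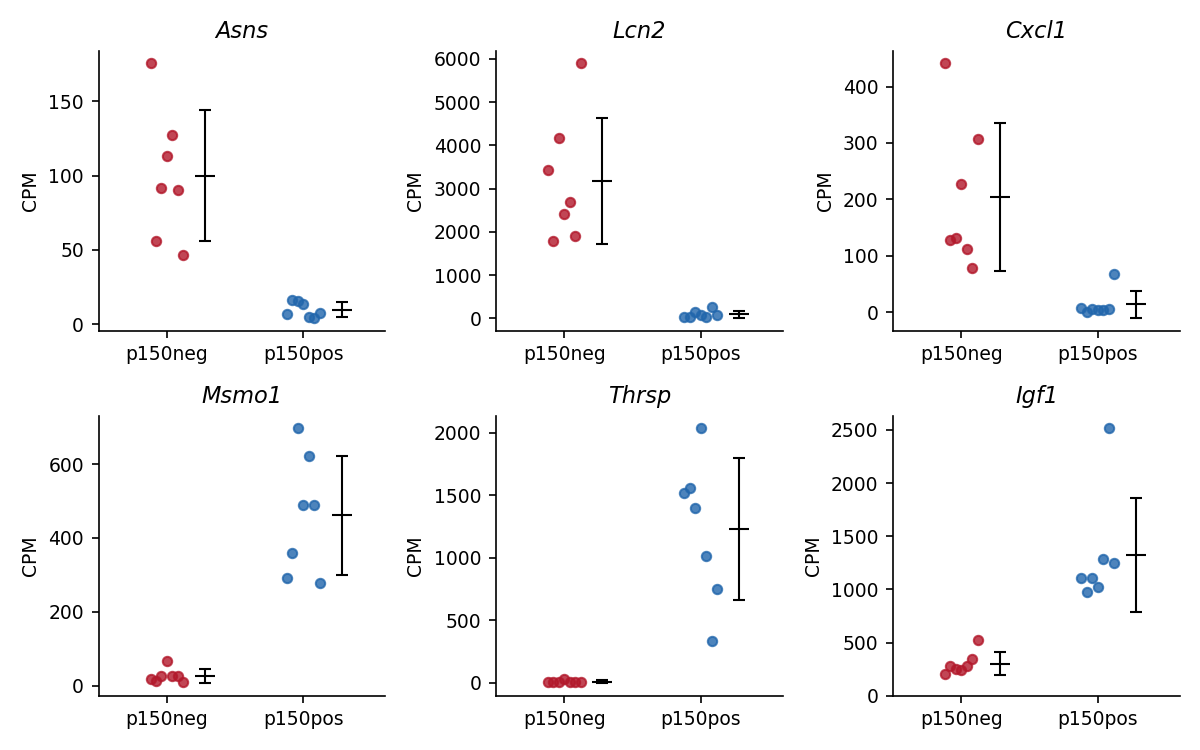
Expression in CPM (linear axes) of 6 genes in each of the 7 p150-negative and 7 p150-positive livers that passed the tissue check, with mean and SD beside the points. Asns, Lcn2 and Cxcl1 are higher and Msmo1, Thrsp and Igf1 lower in p150-negative animals, for example 26.3 against 461 CPM for Msmo1.

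The interferon-stimulated list rose in liver: 23 of its 50 tested members were called higher over all labelled libraries (34 adjusted over the list alone). In the tissue-checked fit 38 were (43 adjusted over the list alone), and none was lower. Its median log2 fold change was 1.47 and 1.66. The set test (limma's camera with a preset correlation) gave adjusted p = 2.16e-10 and 1.83e-30, with 0.467 and 0.0347 with an estimated correlation. Among its members, Oas1g, an oligoadenylate synthetase that senses double-stranded RNA, rose by 3.95 ± 0.43 (adjusted p = 4.12e-06) and Irf7, an interferon-inducible transcription factor, by 2.63 ± 0.30 (7.7e-06). Isg15 rose by 2.36 ± 0.40 (4.11e-04) and Ifit1 by 2.68 ± 0.36 (3.19e-05). Of the GBP and IRG GTPases and other genes that respond to interferon gamma, 1 of 19 was called over all libraries (1 adjusted over the list alone). In the tissue-checked fit 4 were (5 adjusted over the list alone). Gbp9 stood at 1.71 ± 0.42, and the list had adjusted p = 0.325 with an estimated correlation. Of 19 MHC class I and immunoproteasome genes, 2 and then 5 were called higher (2 and 7 adjusted over the list alone). They include H2-Q6 and H2-D1, and adjusted p = 0.166 with an estimated correlation in the tissue-checked fit. Of the RNA sensing and editing genes, 2 and then 6 of 16 were called higher (5 and 10 adjusted over the list alone, with 1 lower in the latter). Ikbke stood at 1.35 ± 0.29 and Dhx58 at 1.64 ± 0.36, with adjusted p = 0.0742 with an estimated correlation. Eif2ak2 (PKR, 0.69 ± 0.27, adjusted p = 0.115) and Ifih1 (MDA5, 0.69 ± 0.27, 0.12) did not pass, nor did Mavs (-0.43 ± 0.19, 0.167) and Adarb1 (0.06 ± 0.46, 0.967). Zbp1, which binds Z-form nucleic acids and can start necroptosis, rose by 1.57 ± 0.47 in the tissue-checked fit (0.0327; 0.269 over all labelled libraries). Ifnb1 was too low to be tested in any tissue. Of the cytokines and chemokines, 4 of 10 members and then 5 of 9 were called higher (5 and 6 adjusted over the list alone). Cxcl1 stood at 3.92 ± 0.71 and Ccl2 at 3.64 ± 0.68, with adjusted p = 0.177 and 0.0347 with an estimated correlation.

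Markers of myeloid cells rose in the same livers. All 11 tested neutrophil markers were called higher in the tissue-checked fit (11 adjusted over the list alone) and 8 over all libraries (11 adjusted over the list alone). Their median log2 fold change was 2.93, with adjusted p = 0.0134 with an estimated correlation (0.467 over all libraries). Mmp8, a granule collagenase, rose by 4.47 ± 0.55 and S100a8 by 3.89 ± 0.51. Of 18 macrophage and monocyte markers, 16 were called higher (18 adjusted over the list alone; 7 and 11 over all libraries). Marco stood at 3.61 ± 0.27, Cd14 at 4.06 ± 0.38 and Ly6c2 at 3.63 ± 0.42, with adjusted p = 0.0164 with an estimated correlation (0.467 over all libraries). Of 25 acute phase genes, 20 were called higher (23 adjusted over the list alone; 10 and 12 over all libraries). Their median was 1.91, with adjusted p = 0.0134 with an estimated correlation (0.663 over all libraries). Orm2 rose by 5.44 ± 0.81, Saa2 by 5.17 ± 0.68 and Serpina3n by 2.77 ± 0.30. The other genes with the largest increases in this fit were Igdcc4 (6.50 ± 0.65), Il1r2 (5.66 ± 0.76), Ccr1 (5.26 ± 0.58), Ubd (4.95 ± 0.67), Slc4a9 (4.91 ± 0.74), Ifitm6 (4.82 ± 0.54) and Myo15b (4.76 ± 0.55). Over all labelled libraries the ranking also held Napsa (8.04 ± 1.73), Gpx3 (6.88 ± 1.66), Ldhb (5.44 ± 1.37) and S100g (5.14 ± 1.45). Without the library of animal 2, Gpx3 came to 1.67 ± 0.33, Ldhb to 1.62 ± 0.49 and S100g to 1.73 ± 0.73 (adjusted p = 0.151), and Napsa fell below the expression filter.

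Genes of cholesterol synthesis fell together in liver: 22 of 23 members were called lower over all labelled libraries and 23 in the tissue-checked fit (23 adjusted over the list alone in both). The median log2 fold change was -2.62 and -2.70, and the set test gave adjusted p = 5.06e-38 and 3.12e-35, with 0.0114 and 0.0134 with an estimated correlation. Hmgcs1 changed by -3.91 ± 0.42, Nsdhl by -3.55 ± 0.30 and Tm7sf2 by -3.71 ± 0.29. Of 15 lipogenic genes, 7 and then 9 were called lower (12 and 13 adjusted over the list alone). Fasn, the fatty acid synthase, stood at -2.65 ± 0.43 and Thrsp at -7.29 ± 0.67, with adjusted p = 0.0415 and 0.0269 with an estimated correlation. In the growth hormone and IGF list, 6 and then 7 of 16 members were called lower and 1 and then 2 higher (7 and 9 lower and 2 higher adjusted over the list alone). The set test gave adjusted p = 0.0956 and 0.00744 with an estimated correlation. Igf1, the hormone that carries much of the effect of growth hormone on body growth, fell by 2.11 on the log2 scale (SE 0.27; adjusted p = 1.97e-05), from 1322 ± 539 to 303 ± 108 CPM. Its binding partner Igfals changed by -3.27 ± 0.32, the receptor gene Ghr by -1.55 ± 0.16 and Mup3 by -7.95 ± 0.57. Of 30 hepatocyte metabolic genes, 4 and then 7 were called lower (4 and 10 adjusted over the list alone), with Cyp1a2 at -3.95 ± 0.40; adjusted p = 0.582 and 0.0803 with an estimated correlation. The other genes with the largest decreases were Ces3b (-7.13 ± 0.48), Ces3a (-7.08 ± 0.39), Cyp2c69 (-5.16 ± 0.42) and Serpina1e (-5.06 ± 0.63), all members of families with near-identical copies. Of 10 fetal and imprinted growth genes, 6 were called higher (6 adjusted over the list alone; 4 of 12 and 6 over all libraries). Among them were Gpc3 at 3.10 ± 0.35, Afp at 3.04 ± 0.61 and Peg3 at 2.31 ± 0.38, and adjusted p = 0.0564 over all libraries and 0.0165 in the tissue-checked fit with an estimated correlation.

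Targets of ATF4 and the integrated stress response, which eIF2 kinases switch on, rose in part in liver. Over all labelled libraries 3 of 27 members were called higher (7 adjusted over the list alone). In the tissue-checked fit 4 of 25 were (5 higher and 1 lower adjusted over the list alone). The medians were 0.91 and 0.73. The set test gave adjusted p = 0.00286 and 5.17e-04, with 0.177 and 0.0347 with an estimated correlation. Besides Asns, Trib3 rose by 2.24 ± 0.43 (0.00116) and Atf3 by 2.49 ± 0.68 (0.0198). Ddit3 (CHOP) rose by 1.42 ± 0.42 in the tissue-checked fit (0.0322) and missed the threshold over all labelled libraries (0.0824). Atf4 (0.42 ± 0.22, 0.277), Chac1 (0.84 ± 0.46, 0.289) and Gdf15 (1.21 ± 0.48, 0.124) did not pass, and Fgf21 was too low to be tested in any tissue. None of 20 cytosolic aminoacyl-tRNA synthetase genes was called by edgeR in either fit (0 adjusted over the list alone; set test adjusted p = 0.598 and 0.823). Of 21 chaperones of the unfolded protein response, 3 were called lower in both fits (4 adjusted over the list alone), with Manf at -0.98 ± 0.24; adjusted p = 0.32 and 0.166 with an estimated correlation. Of 14 p53 targets, 3 were called higher over all libraries and 4 higher and 1 lower in the tissue-checked fit (4 higher and 1 lower adjusted over the list alone in both). Btg2 led them at 2.74 ± 0.25, with adjusted p = 0.046 and 0.0734 with an estimated correlation. Cdkn1a, the cell-cycle inhibitor p21, rose by 1.97 ± 0.45 (0.00561).

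**Figure D3:**
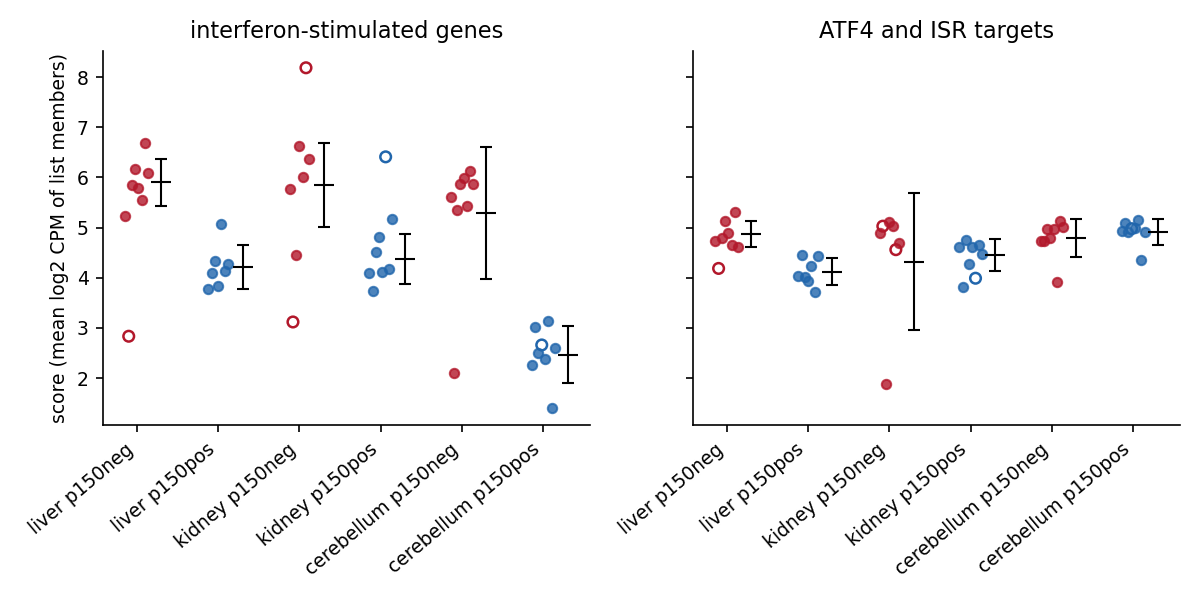
Score of each library (mean log2 CPM of the list's members) for the interferon-stimulated list and the ATF4 and integrated stress response list, by tissue and genotype. Bars give mean and SD of the libraries that passed the tissue check, and open points failed it; the interferon score averages 5.29 against 2.47 in cerebellum, and the stress response score 4.87 against 4.12 in liver.

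In kidney, the libraries that passed the tissue check (5 p150-negative, 7 p150-positive) showed more mRNA of interferon-stimulated, MHC class I and neutrophil genes and less of several tubular transporters in p150-negative animals. Lgals3bp, a secreted interferon-inducible glycoprotein, stood at 671 ± 228 CPM (SD, n = 5) against 129 ± 38.2 CPM (n = 7), a log2 fold change of 2.39 ± 0.25 (SE; adjusted p = 2.8e-04). Isg15 rose by 2.32 ± 0.31 (0.002), Irf7 by 2.33 ± 0.34 (0.00405), Ifit1 by 2.23 ± 0.41 (0.0143) and Cxcl10, a chemokine induced by interferons, by 3.71 ± 0.60 (0.00664). Slc5a2, the glucose transporter of the proximal tubule, changed by -1.89 ± 0.32 (0.00854). The planned fit of all 15 labelled kidneys called 1 gene, Rbm3, a cold-inducible RNA-binding protein, by edgeR (1.46 ± 0.20, adjusted p = 0.0169), although 706 of 11665 genes had an unadjusted p under 0.05 and DESeq2 called 42. The tissue-checked fit called 46 higher and 37 lower of 11957, Rbm3 among them (1.28 ± 0.20, 0.00537). Without the shallowest library as well, that of animal 3, it called 119 higher and 92 lower (4 against 7 animals). All other kidney calls below therefore rest on leaving out 3 libraries, a choice made after the data were seen. With the first part of the animal identifier as a block, 0 genes were called over all libraries and 32 in the tissue-checked fit.

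None of the 47 interferon-stimulated genes was called in kidney over all labelled libraries by edgeR (18 adjusted over the list alone), and 19 were in the tissue-checked fit (36 adjusted over the list alone), all higher. The median log2 fold change was 1.72 and 1.64, and the set test gave adjusted p = 1.06e-15 and 9.6e-56, with 0.233 and 0.00759 with an estimated correlation. In the tissue-checked fit, 2 of 17 GTPases and other genes that respond to interferon gamma were called higher (13 adjusted over the list alone). Over all libraries none was (1 adjusted over the list alone). Ifi47 stood at 2.22 ± 0.39, with adjusted p = 0.0443 with an estimated correlation (0.482 over all libraries). Of 18 MHC class I and immunoproteasome genes, 6 were called higher (7 adjusted over the list alone, and none in either way over all libraries). They include H2-K1 at 1.51 ± 0.22 and B2m at 1.26 ± 0.21, with adjusted p = 0.0443 with an estimated correlation (0.42 over all libraries). Of 4 neutrophil markers, S100a8 was called (3.48 ± 0.64; 3 adjusted over the list alone in both fits), and the set test gave adjusted p = 0.028 over all libraries and 0.00759 in the tissue-checked fit with an estimated correlation. Of 19 renal injury markers, Cdkn1a was called (1.88 ± 0.35, 0.0163; 3 adjusted over the list alone), while Havcr1 (KIM-1) at 2.49 ± 0.73 (0.18) and Lcn2 at 2.35 ± 0.70 (0.18) were not; adjusted p = 0.028 and 0.00759 with an estimated correlation. Of 28 proximal tubule genes, Slc5a2, Slc22a2 and Slc22a12 were called lower and Cyp24a1, a vitamin D-inactivating enzyme, higher at 2.11 ± 0.34 (11 lower and 2 higher adjusted over the list alone). The list had adjusted p = 0.125 with an estimated correlation (0.482 over all libraries). Of 21 genes of the loop of Henle, distal tubule and collecting duct, 1 was called higher and 1 lower (2 and 1 adjusted over the list alone). The direction of their set test differed between the fits (adjusted p = 0.0176, down, over all libraries and 0.00585, up, in the tissue-checked fit; 0.657 and 0.23 with an estimated correlation).

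Hemoglobin mRNA was lower in p150-negative kidneys: Hbb-bs stood at 1314 ± 470 against 3589 ± 1260 CPM (-1.44 ± 0.30, adjusted p = 0.0323) and Hba-a1 at -1.38 ± 0.30 (0.0463). They were the 2 of 7 erythroid markers called (6 adjusted over the list alone; 5 over all libraries), with adjusted p = 0.0542 and 0.0879 with an estimated correlation. None of 29 ATF4 and stress response targets was called by edgeR in kidney in either fit, with 1 adjusted over the list alone in the tissue-checked fit. Their median was 0.28 over all libraries (set test adjusted p = 0.0255; 0.482 with an estimated correlation) and 0.18 in the tissue-checked fit (0.14). Asns stood at 1.05 ± 0.57 (0.702), Atf3 at 2.30 ± 0.60 (0.113), Trib3 at 1.12 ± 0.67 (0.748), Ddit3 at -0.37 ± 0.53 (0.965), Atf4 at 0.03 ± 0.38 (0.997) and Gdf15 at 0.62 ± 0.45 (0.842). Zbp1 (3.00 ± 0.69, 0.0598), Ifih1 (2.57 ± 0.63, 0.0822), Eif2ak2 (0.71 ± 0.45, 0.771), Mavs (0.13 ± 0.28, 0.979), Adarb1 (0.64 ± 0.60, 0.909) and Igf1 (-1.12 ± 0.48, 0.527) also missed the threshold. The genes with the largest increases were Apol9a (4.46 ± 0.92), Serpina3g (4.42 ± 0.90), Ifi206 (4.27 ± 0.71), Oas2 (4.04 ± 0.80), Oas1g (3.79 ± 0.77), Pcdh9 (3.70 ± 0.69) and Oas1a (2.87 ± 0.47), together with Cxcl10, S100a8 and Adam23. Adam23 had 109 counts in the p150-negative and 1 count in the p150-positive kidneys, a ratio of 189 after scaling to CPM, with a 95% counting interval from 33.2 to 7524. Large decreases were Slc10a1 (-5.14 ± 0.57), Car3 (-4.50 ± 0.97), Aspg (-3.93 ± 0.67), Serpina1f (-3.71 ± 0.55) and Slc16a14 (-3.56 ± 0.67).

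In cerebellum, p150-negative animals had far more mRNA of interferon-stimulated genes, together with more of C1qa, C1qb, C1qc and C4b and less of Alas2, Hba-a1 and Aqp4. Usp18, the enzyme that removes ISG15 from proteins, stood at 194 ± 85.8 CPM (SD, n = 8) against 4.91 ± 3.63 CPM (n = 7), a log2 fold change of 5.37 ± 0.64 (SE; adjusted p = 1.83e-04). Ifit1 rose by 5.07 ± 0.68 (3.84e-04), from 9.43 ± 6.50 to 303 ± 142 CPM, and Ifi27l2a by 6.01 ± 0.73 (1.83e-04). Lcn2 rose by 4.56 ± 0.52 (1.65e-04), while the water channel gene Aqp4 of astrocytes fell by 0.96 (SE 0.18; 0.0081). Usp18 and Ifit1 lay above the p150-positive median in 7 of 8 p150-negative animals, the exception being animal 2, and Lcn2 in 8 of 8. Over all labelled cerebella (8 against 8), 90 of 12971 genes were higher and 31 lower in p150-negative animals; 84 and 9 differed by a log2 fold change of at least 1. Without the library of animal 7, which failed the tissue check, the counts were 95 and 36 of 13146, holding 81 of the 90 and 24 of the 31. DESeq2 called 254 genes and limma's voom 41 over all labelled cerebella.

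Of 43 interferon-stimulated genes tested in cerebellum, 34 were called higher over all libraries (43 adjusted over the list alone), and 37 of 46 in the tissue-checked fit (45 adjusted over the list alone), with medians of 3.05 and 3.23. The set test gave adjusted p = 1.04e-36 and 5.03e-34, with 0.0734 and 0.095 with an estimated correlation. Rtp4 rose by 4.26 ± 0.49, Ddx60 by 5.63 ± 0.90, Oasl2 by 5.35 ± 0.78, Irf7 by 4.46 ± 0.61 and Isg15 by 3.94 ± 0.56. Of the GTPases and other genes that respond to interferon gamma, 9 of 17 and then 8 of 18 were called higher (13 and 14 adjusted over the list alone). Irgm1 stood at 3.29 ± 0.38 and Gbp6 at 4.32 ± 0.65, with adjusted p = 0.0885 and 0.109 with an estimated correlation. Of the MHC class I and immunoproteasome genes, 10 of 16 and then 11 of 18 were called higher (14 and 17 adjusted over the list alone). H2-T23 stood at 2.63 ± 0.32, and the set test gave adjusted p = 0.0419 and 0.0688 with an estimated correlation. The RNA sensors Ddx58 (RIG-I, 3.73 ± 0.56), Dhx58 (2.74 ± 0.49) and Ifih1 (MDA5, 3.44 ± 0.62) were the 3 of 15 RNA sensing and editing genes called higher in both fits (3 adjusted over the list alone); adjusted p = 0.418 and 0.401 with an estimated correlation. Eif2ak2 rose by 2.44 ± 0.41 (0.00249) and Zbp1 by 4.10 ± 0.92 (0.0331), whereas Mavs (-0.57 ± 0.45, 0.753) and Adarb1 (0.05 ± 0.18, 0.963) did not pass. Of the cytokines and chemokines, 2 of 7 and then 3 of 8 were called higher (2 and 3 adjusted over the list alone). Cxcl10 led them at 5.41 ± 0.72 with Ccl12 at 4.08 ± 0.72, and adjusted p = 0.162 and 0.109 with an estimated correlation. The other largest increases in the tissue-checked fit were Oas1b (6.35 ± 0.81), Slfn8 (5.95 ± 1.02), Ifi204 (5.60 ± 0.75) and H2-Q7 (5.50 ± 0.80), and over all libraries also Lrg1 (4.82 ± 0.59), Phf11d (4.73 ± 0.72) and Oas1a (4.55 ± 0.62). Ifi211 had 125 counts against 1, a ratio of 111 after scaling to CPM, with a counting interval from 19.5 to 4411.

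No target of ATF4 and the integrated stress response passed the test in cerebellum: edgeR called 0 of 31 in either fit (0 adjusted over the list alone), with medians of -0.07 and -0.10 and a set test that leaned upward (adjusted p = 0.929 and 0.941). Asns stood at 156 ± 31.2 against 196 ± 25.0 CPM (-0.29 ± 0.13, 0.464), Ddit3 at -0.21 ± 0.19 (0.802), Atf4 at -0.15 ± 0.14 (0.802) and Chac1 at -0.01 ± 0.38 (0.996), while Atf3, Trib3 and Gdf15 were too low to be tested. Cdkn1a (0.45 ± 0.33, 0.742) and Igf1 (0.17 ± 0.37, 0.933) did not pass. Of 21 chaperones of the unfolded protein response, Pdia4 (-0.73 ± 0.17, 0.0492) and Pdia6 (-0.59 ± 0.14, 0.0419) were called lower in both fits (8 and 5 adjusted over the list alone); adjusted p = 0.0734 and 0.095 with an estimated correlation.

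Some genes of glia moved in either direction. The complement genes C1qa (1.25 ± 0.21, adjusted p = 0.00305), C1qb (1.08 ± 0.20) and C1qc (1.24 ± 0.24) rose. They stand in both the microglia list (4 of 15 called over all libraries and 3 in the tissue-checked fit; 4 and 11 adjusted over the list alone) and the macrophage list (3 of 13 in both; 10 and 8 adjusted over the list alone). With an estimated correlation, adjusted p = 0.11 and 0.0981 for microglia and 0.0419 and 0.0688 for macrophages. Of the reactive astrocyte genes, 4 of 17 and then 5 of 18 were called higher (10 and 9 adjusted over the list alone), including C4b at 2.69 ± 0.39; adjusted p = 0.0419 and 0.0688 with an estimated correlation. Several of them, such as H2-D1 and Psmb8, are also interferon-inducible. Of 14 astrocyte and Bergmann glia markers, 1 and then 3 were called lower (4 and 5 adjusted over the list alone): Aqp4, Fabp7 (-1.17 ± 0.23) and S100b (-0.72 ± 0.14); adjusted p = 0.11 and 0.0896 with an estimated correlation. Of the erythroid markers, 2 of 6 and then 3 were called lower (5 adjusted over the list alone in both). Alas2, the heme synthesis enzyme of red cells, stood at -1.73 ± 0.26 and Hbb-bs at 767 ± 395 against 1788 ± 541 CPM, with adjusted p = 0.0419 and 0.0688 with an estimated correlation. Slc47a1 (-2.96 ± 0.54), Nov (-2.88 ± 0.69), Fam46c (4.82 ± 3.04 against 20.5 ± 8.83 CPM), Hba-a1 (-1.20 ± 0.24), Dio2 (-1.19 ± 0.24) and Gabra2 (-1.15 ± 0.27) were the other large decreases. The myelin gene Ugt8a, called lower over all libraries (-1.33 ± 0.32, 0.0475), came to -0.99 ± 0.25 (0.0651) without the library of animal 7. Of 20 myelin genes it was the 1 called (1 adjusted over the list alone in both fits), with adjusted p = 0.418 and 0.575 with an estimated correlation. None of 15 Purkinje cell or 13 granule cell markers was called by edgeR in either fit (1 Purkinje marker lower adjusted over the list alone in the tissue-checked fit). Their set tests gave adjusted p = 0.0235 and 0.00469 over all libraries, upward, but 0.627 and 0.478 with an estimated correlation. In the tissue-checked fit they gave 0.687, with the direction of the Purkinje list reversed, and 0.642.

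**Figure D4:**
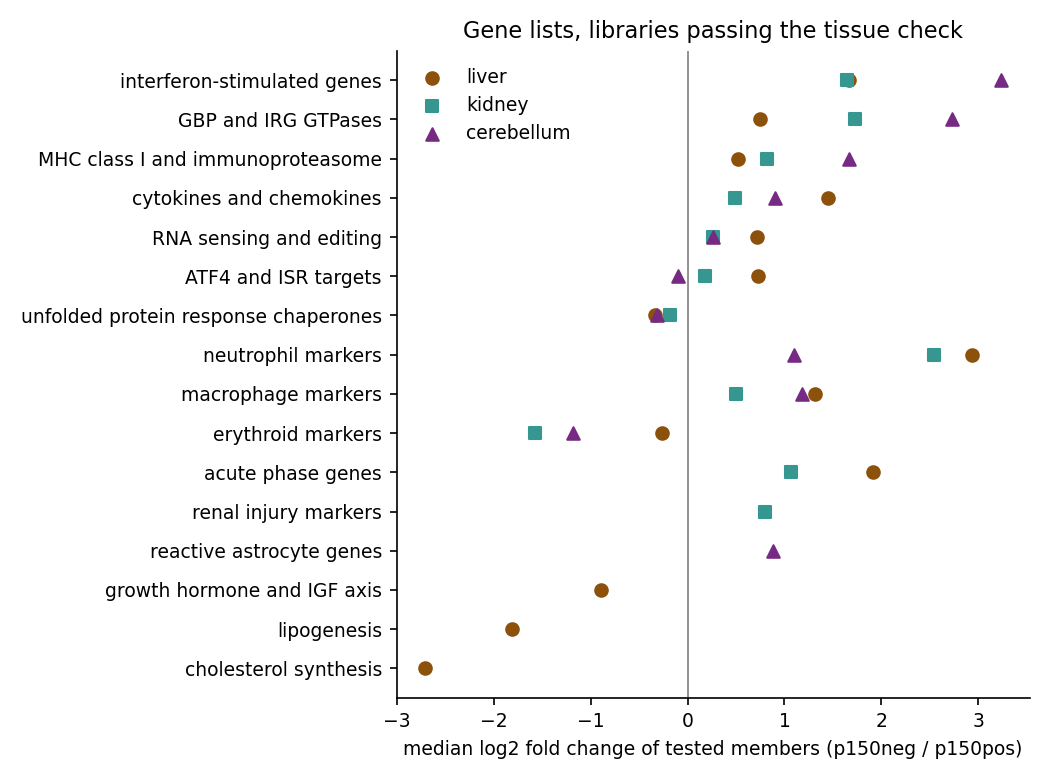
Median log2 fold change (p150-negative over p150-positive) of the tested members of 16 gene lists in the 3 tissues, over libraries that passed the tissue check; some lists were tested in 1 or 2 tissues only. The interferon-stimulated list lies at 1.66 in liver, 1.64 in kidney and 3.23 in cerebellum, and cholesterol synthesis at -2.70 in liver.

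The difference in genotype effect between tissues was tested as an interaction, since the same question was asked in 3 organs of the same animals. Between liver and cerebellum 460 of 14216 genes differed, 320 with the larger (more positive) effect in liver and 140 with the larger effect in cerebellum. Asns was among the former, with an effect larger in liver by 3.54 ± 0.49 (SE; edgeR adjusted p = 5.11e-05), along with Tpd52 (1.92 ± 0.22), Dnajc12 (2.76 ± 0.32), Igdcc4 (7.09 ± 0.97) and Slc25a4 (2.13 ± 0.29). In the other direction stood the lipogenic gene Thrsp (-7.26 ± 0.67) and the fatty acid transporter gene Mfsd2a (-4.99 ± 0.64). So did Msmo1 (-3.16 ± 0.41) and Pmvk (-2.56 ± 0.34) of cholesterol synthesis, and Ntrk2. Ntrk2 fell below the expression filter of the liver fit, so no effect of genotype was estimated for it in liver alone. The interferon-stimulated list had a smaller effect in liver than in cerebellum by a median of 1.76 (that is, -1.76; camera adjusted p = 3.35e-14), with 14 of 51 members called (27 adjusted over the list alone); adjusted p = 0.563 with an estimated correlation. The stress response list had a larger effect in liver (median 0.93, adjusted p = 0.00438), with 2 of 36 members called (4 adjusted over the list alone); adjusted p = 0.538 with an estimated correlation. With the animal as a block 67 genes had the larger effect in liver and 87 in cerebellum, so the excess toward liver did not stay. The estimated-correlation p became 5.17e-04 for the interferon list and 0.0221 for the stress response list. The list results are differences in log2 fold change, not in level. In passing libraries the interferon score of p150-negative animals averaged 5.91 in liver, 5.85 in kidney and 5.29 in cerebellum. That of p150-positive animals averaged 4.22, 4.37 and 2.47. The scores rest on 50, 47 and 43 tested members, so levels compare only roughly between tissues.

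Between liver and kidney 71 of 12743 genes differed, 40 with the larger effect in liver and 31 with the larger effect in kidney. With the animal as a block edgeR called 0 in liver and 6 in kidney (682 genes at an unadjusted p under 0.05), and in the tissue-checked fit with the block 74 and 43. The smallest p among the 31 belonged to Msmo1 (-4.96 ± 0.66, adjusted p = 2.89e-04; -3.93 ± 0.49 in the tissue-checked fit), Tm7sf2 (-3.87 ± 0.58), Erg28 (-2.45 ± 0.41), Cyp51 (-3.97 ± 0.71) and Ugt2b37. Ugt2b37 fell below the expression filter in the liver and the kidney fits over all labelled libraries. Cholesterol synthesis as a list was not tested between tissues. The 40, none of which stayed with the block over all labelled libraries, were led by Dnajc12 (4.51 ± 0.80; 4.36 ± 0.35 in the tissue-checked fit), Slc25a4 (2.39 ± 0.43), Akr1b10 (3.05 ± 0.54), Spink1 (4.47 ± 0.83) and Cgref1 (4.45 ± 0.82). Neither list differed between these tissues by camera over all labelled libraries (interferon-stimulated genes 0.222, stress response 0.222). The interferon list passed by camera with the animal as a block (median -0.11, adjusted p = 0.0127, but 0.741 with an estimated correlation). With the tissue check added to the block it did not pass (median 0.18, camera adjusted p = 0.405). The stress response list passed in the tissue-checked fit with the larger effect in liver (median 0.58, 0.0212; 0.716 with an estimated correlation; 0.0529 with the block added). Between kidney and cerebellum 17 of 14612 genes differed, and with the animal as a block 4. Lrg1 had the larger effect in cerebellum (-4.66 ± 0.80, edgeR adjusted p = 0.00902), and so had Mmp13. Adam23, Ndnf, Rasl10b and Pcdh9 had the larger effect in kidney. Over all labelled libraries, those genes fell below the expression filter of the kidney fit, and Mmp13 below that of the cerebellum fit. No effect of genotype was thus estimated for them in that tissue alone. The interferon list had a smaller effect in kidney than in cerebellum (median -1.67, camera adjusted p = 1.4e-13), with 0 of 51 members called by edgeR (8 adjusted over the list alone); adjusted p = 0.502 with an estimated correlation, and 0.0837 with the animal as a block. In the tissue-checked fit this was 0.747, and it passed there with the block (0.0131, 4 members called) and without animal 2 (0.0255, 8 called). The stress response list did not pass (0.0908). Over libraries that passed the tissue check, 110 genes had the larger effect in liver and 85 in kidney, 192 in liver and 184 in cerebellum, and 9 in kidney and 8 in cerebellum. With the animal as a block these came to 117, 197 and 9 genes per pair.

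Genes called in more than 1 tissue were counted with the animals shared between tissues. In the tissue-checked fits, 20 genes were higher in p150-negative animals in all 3 tissues, against 0.0192 if the tissues were independent, and 15 of them stand on the interferon-stimulated list (0.101 by chance; Fisher's exact test, one-sided, p = 3.52e-32; counted after the data were seen). They were Cxcl10, Ddx60, H2-D1, H2-Q6, H2-Q7, Ifi27, Ifi44, Ifit1, Ifit3, Ifit3b, Irf7, Isg15, Lgals3bp, Oas1a, Oas1g, Oasl2, Rbm3, Rtp4, Usp18 and Xaf1. Usp18, for example, changed by 1.99 in liver, 2.80 in kidney and 5.37 in cerebellum. Bpgm and Nat8f1 were lower in all 3 (Bpgm, a red cell enzyme, at -0.66, -1.61 and -0.75). Over all labelled libraries, liver and cerebellum shared 28 higher genes (3.25 if independent; Fisher's exact test, one-sided, p = 2.15e-19) and 7 lower (0.665; p = 3e-06), and Rbm3 was the 1 gene called in all 3. In the tissue-checked fits liver and cerebellum shared 56 higher genes (29 on the interferon-stimulated list), liver and kidney 30 (17), and kidney and cerebellum 24 (16). Since libraries of 1 animal can deviate together, the independent values are a lower reference. Fisher's exact test also treats genes as independent. Members of the interferon-stimulated list moved together across libraries, with an estimated correlation of 0.377 in the tissue-checked fit of liver and kidney. The p-values of Fisher's test are therefore likely too small.

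Within a genotype, animals with a high interferon score in 1 tissue were compared with their score in another and with their stress response score, 12 relations in all. Over all labelled libraries 4 passed Benjamini-Hochberg adjustment by exact permutation of Pearson's r. Among p150-negative animals, the interferon scores of liver and cerebellum had r = 0.961 (n = 8, exact p = 0.00553, adjusted 0.0166; Spearman's rho = 0.714, exact p = 0.0576), and the interferon and stress response scores of liver r = 0.856 (exact p = 0.00417, adjusted 0.0166; rho = 0.714, exact p = 0.0576). Both rest on animals 2 and 14: without them r was 0.47 and 0.431, and the library labelled liver of animal 2 is 1 of the 5 that failed the tissue check. Among p150-positive animals, the interferon scores of liver and kidney had r = 0.959 (n = 7, exact p = 0.00298, adjusted 0.0166; rho = 0.929, exact p = 0.00675; 0.787 without animals 4 and 12). The library labelled kidney of animal 12, with the highest interferon score of that group (6.41), also failed the tissue check, and without it r was 0.823 (n = 6, adjusted p = 0.17). The interferon and stress response scores of cerebellum had r = 0.944 (n = 8, exact p = 0.00288, adjusted 0.0166; rho = 0.714, exact p = 0.0576; 0.709 without animals 12 and 13). Leaving out the 2 farthest animals also moved relations that had not passed. Among p150-negative animals, interferon against stress response scores went from r = 0.263 to 0.922 in kidney and from 0.163 to 0.885 in cerebellum. The interferon scores of kidney and cerebellum went from 0.731 to 0.885, but those of liver and kidney from 0.687 to -0.326. Few animals remained in each. None of the relations passed over the libraries that passed the tissue check.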

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

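The tests on the 5 libraries of another organ, the tests of swapped animals and of depth for animal 2, the test of the shallowest kidney library in the tissue-checked fit, and the choice of genes anew for placing animal 2 were chosen after the result was seen, and the tissue check itself was added then.

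The first pattern is the 5 libraries that carry the genes of another organ. RNA carried over from other libraries would leave most of the labelled tissue's own genes in place, yet these stood at most at 0.827% of the median of the label. A swap between 2 libraries of the series would need the genes of another sampled tissue, and 1 of the 5, the library labelled liver of animal 2, holds all 4 identity genes of kidney; the others hold stomach, small intestine or Hox and myelin genes. Some hold more than 1 organ, as the kidney library of animal 12 has exocrine pancreas genes (14355 CPM) beside those of small intestine. It remains open that another organ, or tissue around it, or another part of the nervous system in animal 7, was sampled or labelled. The marker set of the other organ stood at least 11.8 times above its highest level in passing libraries of that label. The marker sets of stomach, small intestine, exocrine pancreas, adrenal, myelin and Hox genes were chosen after the most abundant genes of the libraries were seen. Their high levels are therefore no independent test of which organ it was. Where in the handling another organ may have been sampled or labelled was not tested.

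The second pattern is animal 2, p150-negative, whose interferon score lies apart from its group. In liver it is the lowest of 8 (2.84, next 5.23; gap over range 0.623), from the library that failed the tissue check; in cerebellum it is again the lowest of 8 (2.09, next 5.34; 0.806), from a library that passed. Low depth is argued against by that library's 5.47 M counts, the most of its group, and a swap with a p150-positive animal by the 0 p150-positive animals with a score above the lowest of the other p150-negative ones. On 70 genes called without animal 2 and outside the interferon lists, where the p150-positive mean is 0 and the p150-negative mean is 1, it lies at 0.32. A bound set at the highest p150-positive animal (0.133) was too lenient, because those animals had taken part in choosing the genes. With the genes chosen anew without the library placed, the highest p150-positive animal lies at 0.198 and the lowest other p150-negative one at 0.496. The lists do not hold every interferon-inducible gene, and Oas1b, Ifi211, Ifitm3 and others stay among the 45 higher of the 70. On these animal 2 lies at 0.229, below the highest p150-positive animal (0.231). The lowest other p150-negative animal, animal 11, lies at 0.288 on the higher genes chosen without it. Animal 2 is thus not the only p150-negative animal near that bound. On the 25 lower genes animal 2 lies at 0.727, above the highest p150-positive animal (0.305) and within the other p150-negative ones (0.573 to 1.49). The higher and lower genes thus point apart, and a wrong genotype label stays possible. A weaker interferon response of this animal or a mixture stays possible too, and neither was tested.

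The third pattern is the 1 gene called in kidney against 740 in liver and 121 in cerebellum. Leaving out the 3 libraries of other organs gave 83 calls, and 0 of 40 other drawn sets of 3 kidney libraries gave as many (highest 42). A drawn set could hold some of the libraries of other organs, but not all 3. These libraries of other organs are thus a likely part of the cause. The shallowest library, that of animal 3 (0.27 M counts), is another likely part: left out of the tissue-checked fit as well, it took the calls from 83 to 211, while leaving out any other single library gave at most 107. Left out while the 3 libraries of other organs stayed in, it gave 1 call, which decides nothing because those can mask a gain. Fewer passing animals (5 and 7) and the recovery of 65.3% of simulated 4-fold changes in kidney, against 97.8% in liver, leave power and a smaller effect in kidney both open.

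Other splits of the libraries, 100 per result with the real one included, were fitted in the same way. With 100 splits, a share under 1 in 100 cannot be resolved. Chance is unlikely, with only the real split as large, for the 740 genes of liver (highest other split 0). In the tissue-checked liver fit this was 1152 against 6. The same holds for cerebellum (121 against 1, and 131 against 21 in the tissue-checked fit) and for the 83 genes of tissue-checked kidney (highest other 12). Over all labelled kidneys the real split called 1 gene and the highest other 0, which is too small a count to decide by, since that gene is lost in edgeR without a filter, with the identifier block and on leaving out any of 7 single libraries. For the median change of the interferon-stimulated list, only the real split was as large in liver (1.47, highest other 1.36) and in cerebellum (3.05, highest other 2.03). The margin in liver is small, and that fit holds the library labelled liver of animal 2, which failed the tissue check. In kidney, over all labelled libraries, chance cannot be excluded for that median (1.72, highest other 1.98, with 5 splits as large). Between liver and kidney 2 of the 100 splits, the real one included, called as many interaction genes (71, highest other 88). That fit ignores the animal, and with the animal as a block 0 and 6 genes were called instead of 40 and 31. Chance is therefore not excluded there. Chance is unlikely for the interaction between liver and cerebellum (460, 1 split as large, highest other 2). It cannot be excluded between kidney and cerebellum (17; 8 splits as large, highest other 122). A split with several times the calls of the real one, 122 against 17, points to a structure among these libraries other than genotype. It was not traced to a tissue, and over the kidney libraries alone the highest other split was 0. All interaction splits used the labelled libraries, including those that failed the tissue check. For this pair these were 3 kidneys and the cerebellum of animal 7. Interaction splits were not drawn over passing libraries. Whether the libraries of other organs made this structure, or hid a difference in the pairs with kidney, was thus not tested.

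Differences between tissues in the effect of genotype were listed because genes passed the test of the interaction. These were 71 genes between liver and kidney, 460 between liver and cerebellum and 17 between kidney and cerebellum. Chance was not excluded for the first and the last pair, as given above. Among lists, the interferon-stimulated genes differed between liver and cerebellum (camera adjusted p = 3.35e-14) and between kidney and cerebellum (1.4e-13), and the stress response targets between liver and cerebellum (0.00438), each of which was lost with an estimated correlation in these fits (0.563, 0.502 and 0.538). With the animal as a block, which pairs the tissues, the estimated-correlation values passed between liver and cerebellum (5.17e-04 for interferon-stimulated genes, 0.0221 for stress response targets). Between kidney and cerebellum the interferon list missed with the block (0.0837) and passed with the block and the tissue check (0.0131).

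Single animals stood far from their group in 7 of 18 groups of scores and Adar values, where chance gives about 1 in 20. Besides animal 2, these were animal 3 in kidney, with the lowest stress response score (1.89, next 4.56; gap over range 0.831) and the lowest Adar (0 counts in a library of 0.27 M; 0.846). In cerebellum, animal 11 had the lowest stress response score of p150-negative animals (3.92, next 4.74; 0.68) and the highest Adar (0.605), in a library of 0.94 M counts. Animal 13, p150-positive, had the lowest stress response score of its group in cerebellum (4.36, next 4.91; 0.704). No explanation was tested for these.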

How the results depend on the processing

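The tissue check, its combinations and the leaving out of single libraries were chosen after the data were seen. Of the values of named genes under the alternatives, 597 stayed on the same side of the threshold, 37 passed newly and 26 no longer passed. There were 0 changes of direction where either value passed. Many named genes were chosen as the largest passing changes in these fits, and the alternatives reuse the same libraries. A steady direction was therefore likely from the start and is a weak test. Changes of direction where neither passed count among the 597, as for Adar in kidney (-0.005 in the planned fit, 0.061 with DESeq2).

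Called genes, 740 in liver, 1 in kidney and 121 in cerebellum, came with DESeq2 to 1128, 42 and 254, and with voom to 41 in cerebellum. In kidney they came to 0 without a filter and with the identifier block, and to 351 with 1 fit of all tissues. That fit gave 868 higher and 208 lower genes in liver (441 and 299 in the planned fit, of which it kept 269 and 151), 290 and 61 in kidney, and 98 and 7 in cerebellum (90 and 31). With the tissue check they came to 1152 and 83, with DESeq2 added 1430, 306 and 290, with the identifier block 1348 and 32, with Xist 68 in kidney, and also without animal 2 and shallow libraries 1149, 211 and 219. Leaving out 1 library gave 472 (animal 8; 277 of them higher) to 1152 (animal 2; 683 higher) in liver, 86 to 160 in cerebellum (13 to 51 lower, 2 to 16 lower by at least 1 on the log2 scale, without animal 12 and animal 11) and 0 to 5 in kidney, where Rbm3 was lost without animal 1, 4, 6, 7, 9, 10 or 15, and where 5 and 3 genes were called without animals 2 and 12. In the tissue-checked kidney fit it gave 34 (animal 8) to 211 (animal 3).

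Interactions are given as genes with the larger effect in the first and in the second tissue. Liver against kidney, 40 and 31, came to 0 and 6 with the animal as a replicate block, 265 and 92 with DESeq2, 110 and 85 with the tissue check (the same counts without animal 2), 74 in liver when the block was added, and 21 in liver without a filter. Liver against cerebellum, 320 and 140, came to 67 and 87 with the block, 539 and 241 with DESeq2, and in liver to 192 with the tissue check, 171 also without animal 2 and 86 with the block added. Kidney against cerebellum, 14 and 3, came to 1 in kidney with the block, 112 and 26 with DESeq2, 1 in cerebellum without a filter, 9 and 8 with the tissue check, 23 in cerebellum also without animal 2, and 2 and 7 with the block added. Over all labelled libraries the block fits kept 14, 15 and 15 of the 16 animals, so few were lost. With the tissue check they kept 11, 13 and 11. These fits also estimate a level for each animal, which leaves fewer degrees of freedom. Why the counts changed was not tested.

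Shared higher genes came with DESeq2 to 12 (liver and kidney), 48 (liver and cerebellum), 7 (kidney and cerebellum) and 6 (all 3), with the tissue check to 30, 56, 24 and 20, and with an absolute log2 fold change of at least 1 added to 27, 49, 23 and 18; that limit alone gave 0 for kidney and cerebellum and for all 3. Shared lower genes came to 5 and 19 with DESeq2 (liver with kidney, liver with cerebellum), to 13, 4 and 2 with the tissue check (liver and kidney, kidney and cerebellum, all 3), to 9, 0 and 2 with the limit added (liver and kidney, liver and cerebellum, kidney and cerebellum), and to 0 in liver and cerebellum with the limit alone.

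Lists past the threshold numbered 3, 3 and 4 in liver, kidney and cerebellum with an estimated correlation (10, 7 and 0 with the tissue check) and 11, 4 and 8 with fry (9 in kidney and 10 in cerebellum with the tissue check); between tissues an estimated correlation left 0 in each pair in both. With the preset correlation, the tissue check with the animal block left 4 between liver and kidney. The interferon-stimulated list missed with an estimated correlation in liver (0.467), kidney (0.233) and cerebellum (0.0734, tissue check 0.095), and with fry in liver (0.112) and kidney (0.25). Between liver and cerebellum it missed with an estimated correlation at 0.563 (tissue check 0.524), yet passed when the animal was the block (5.17e-04, tissue check 0.00402) and in the tissue check without animal 2 (0.0187). Between kidney and cerebellum it missed at 0.502 (tissue check 0.747; 0.0837 with the block) and passed in the tissue check with the block (0.0131) or without animal 2 (0.0255). Between liver and kidney it passed by the preset correlation with the animal block (0.0127), but not with the tissue check added to the block (0.405). Stress response targets passed by the preset correlation in the tissue check (0.0212). Stress response targets missed in liver with an estimated correlation (0.177) and in kidney with it (0.482), fry (0.599), the identifier block (0.0596), no filter (0.21) and the tissue check (0.14; 0.646 with an estimated correlation, 0.796 with fry, 0.14 without animal 2 and with the identifier block).

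With the tissue check, alone or with a further choice, 24 list values reversed direction where the planned or the new value passed. Loop of Henle and distal tubule genes in kidney did so with the check alone (0.00585), without animal 2 (0.00585), with an estimated correlation (0.23), fry (0.352) and the identifier block (0.0231). Purkinje markers did so in the same settings, in that order (0.687, 0.604, 0.92, 0.848, 0.507). Endothelial markers did so in kidney (0.957 alone, 0.957 without animal 2, 0.983 with an estimated correlation) and between liver and kidney (0.496, 0.496, 0.858, and 0.296 with the animal block). Neutrophil markers did so between liver and kidney (0.0212 alone and without animal 2), and T and NK cell markers between kidney and cerebellum (0.0449 alone). The rest counted only with a further choice. T and NK cell markers in liver (0.036) and fibrillar matrix in kidney (0.945) turned with fry. Granule cell markers turned with the identifier block (0.887), and proliferation between liver and kidney with the animal block (0.668). For the lists counted with the check alone, the construction shows part of the cause, since organs with other cell types were left out.

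The 4 relations of scores came under the tissue check to r = 0.68, 0.742, 0.823 and 0.943 (exact permutation, adjusted p = 0.211, 0.17, 0.17 and 0.0589), over 9 relations with fewer animals. Depth limits genes under about 10 CPM in the shallowest libraries.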

Other observations

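The prediction tested here was written before its values were looked up, on a pattern seen in these data. Rbm3 and Cirbp code for RNA-binding proteins that rise when cells cool, and Rbm3 was called higher in p150-negative animals in all 3 tissues over all labelled libraries (1.59 ± 0.19 in liver, 1.46 ± 0.20 in kidney, 0.99 ± 0.19 in cerebellum; SE, edgeR). A lower body temperature of these animals may contribute. It would predict Cirbp higher as well: Cirbp was called higher in 2 of the 3 tissues (2.08 ± 0.44 in liver, adjusted p = 0.00705; 1.18 ± 0.26 in cerebellum, 0.0311) and missed the threshold in kidney (1.71 ± 0.49, 0.655). Heat shock genes, which fall on cooling, had median log2 changes of -0.41 in liver, -0.57 in kidney and -0.30 in cerebellum, with a value under 0 in 9 of 10, 10 of 12 and 9 of 11. Most of these single changes did not pass the test; those of Hsph1 (-1.09 ± 0.26, adjusted p = 0.0164) and Dnaja1 (-0.81 ± 0.18, 0.00734) in liver did. No temperature is recorded in the labels, and less food or slower growth could move the same genes, so this stays a hypothesis.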
